A study of Rattus norvegicus with 6 samples.

How the data were processed

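RNA from neonatal rat ventricular cardiomyocytes was measured in 6 libraries, 3 control and 3 erastin (10 µM for 24 h), and samples were grouped by their titles. Per the labels' protocols, poly(A) RNA was fragmented, libraries were made with dUTP marking of the second strand, and paired ends were sequenced on an Illumina NovaSeq. HISAT2 2.0.5 and DESeq2 are named in the submitters' processing notes with no role, and the counting tool, genome build and annotation are not given in the sources used here. The authors deposited 1 table of FPKM for 34052 features, with the 6 libraries as columns. It holds 32883 Ensembl gene IDs and 1169 features named outside the Ensembl numbering. FPKM is scaled by the library total, so a change in a few abundant features shifts the values of all others.

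The unit and depth were checked on the values. Of the FPKM above 0 of tested features, 99.98% equalled, within a relative tolerance of 1e-06, a whole number of reads times a step set by the library total and a counted length. The recovered totals were 11508364, 14914827 and 11506854 reads in control replicates 1 to 3 and 11149351, 12017459 and 11126968 in erastin replicates 1 to 3. Of the tested features, 99.98% had a counted length within 0.02 of a whole number. In a single simulated table, drawn with the recovered totals and lengths, this recovery gave the exact reads for 99.16% of 13528 features and all 6 library totals. For pairs of libraries within a group the mean chi-square per feature was 2.96 to 5.41, above sampling noise. The median was 0.60 to 0.77, so a minority of features carries most of the excess. These medians are also above the median that sampling noise alone gives, so the typical feature varied beyond counting noise too. No library was counted as a copy of another.

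The main test was limma 3.58.1 in R 4.3.3 on log2(FPKM + 1), with a trended and robust prior and Benjamini-Hochberg adjustment at 0.05. Features with at least 1 FPKM in at least 3 libraries were tested, which left 13576, of which 647 were named outside the Ensembl numbering. A fold change on this scale understates the change of low features, and folds of mean FPKM are given beside it. The main test followed the deposited unit, FPKM, in place of the planned count test, and the recovered reads were used in an alternative with limma's voom method. The test was checked on 10 simulated tables for erastin against control with 200 changed features and 13432 to 13490 features tested. It recovered 15% of features changed 1.25-fold, 60% of those changed 1.5-fold, 87% of those changed 2-fold and 96% of those changed 4-fold. In these simulations 10.9% of the calls were false, above the nominal 5%, against 5.5% for limma's voom method on the simulated reads. The simulated tables had far fewer changed features than were called in the data, and the same dispersion for every feature. The share of false calls and the shares recovered depend on how many features truly change. Neither carries over to the calls in the data. Shares and counts per library were compared with exact two-sided permutation tests.

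Features were to be named, before the data were examined, by gene symbol and by 38 gene lists. The reference table, of assembly GRCr8, matched 0 of the 34052 IDs, so gene symbols and gene lists were not analysed here. This left the part of the rule that takes the largest increases and decreases among Ensembl-numbered features past the adjusted p whose groups do not overlap and whose mean is at or above the median. The first 2 in each direction are printed by ID and the first 10 are summarised. The alternatives fixed before the data were examined were the replicate number as a block, each library left out, pseudocounts of 0.1 and 0.01, no filter, a mean of at least 5 FPKM, centring on the median log ratio, quantile normalization, a constant prior, an absolute log2 fold change of at least 1 and an adjusted p under 0.01. Voom on the recovered reads, with and without centring, leaving out the 100 most abundant features, and shares of recovered reads were added after the data were seen. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 was used for the recovery and the figures.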

Results

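The transcriptome of neonatal rat ventricular cardiomyocytes, muscle cells isolated from the ventricles of newborn rats and kept in culture, was measured by poly(A)-selected, strand-marked RNA sequencing. Cells treated with 10 µM erastin for 24 h (n = 3 libraries) were compared with control cells (n = 3 libraries). Erastin blocks the cystine/glutamate antiporter and is used to induce ferroptosis, an iron-dependent form of cell death with lipid peroxidation. The comparison asked which transcripts change in cardiomyocytes under this treatment. The values were FPKM (fragments scaled by the length of the feature and the total of the library) for 34052 features, of which 22354 had a value above 0 in at least 1 library. Library totals recovered from the FPKM steps were 11508364, 14914827 and 11506854 reads for control replicates 1, 2 and 3, and 11149351, 12017459 and 11126968 reads for erastin replicates 1, 2 and 3. The median tested feature had 304 reads in a library. The labels do not say that the 3 libraries of a group came from separate cultures or litters, so the p-values measure only the spread between these libraries, which may be technical.

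Most tested features differed in FPKM between erastin and control libraries. Of 13576 features tested with limma, 5744 rose and 3267 fell at a Benjamini-Hochberg adjusted p under 0.05, and 4565 did not pass. Most of these changes were small, with a median absolute log2 fold change of 0.48 among the changed features. At least 2-fold changes were found for 699 rising and 645 falling features, at least 4-fold changes for 98 and 88, and at least 8-fold changes for 20 and 12. The median standard error of a log2 fold change was 0.071. The 3 control and 3 erastin values did not overlap in 9773 features (72%), where chance gives 10%. Libraries of the same group correlated across features with r between 0.985 and 0.989, and libraries of different groups with r between 0.925 and 0.935, where features are not independent replicates.

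The balance of rising and falling features depended on the scaling of the libraries. As deposited, 63.7% of the changed features rose. After each library was centred on its median log ratio, which moved erastin against control by 0.14 on the log2 scale, 4231 features rose and 4271 fell, so that 49.8% of the changed features rose. At the 2-fold level the centred values gave 528 rising and 832 falling features. Log2 fold changes relative to this shift are given below as centred values.

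**Figure D1:**
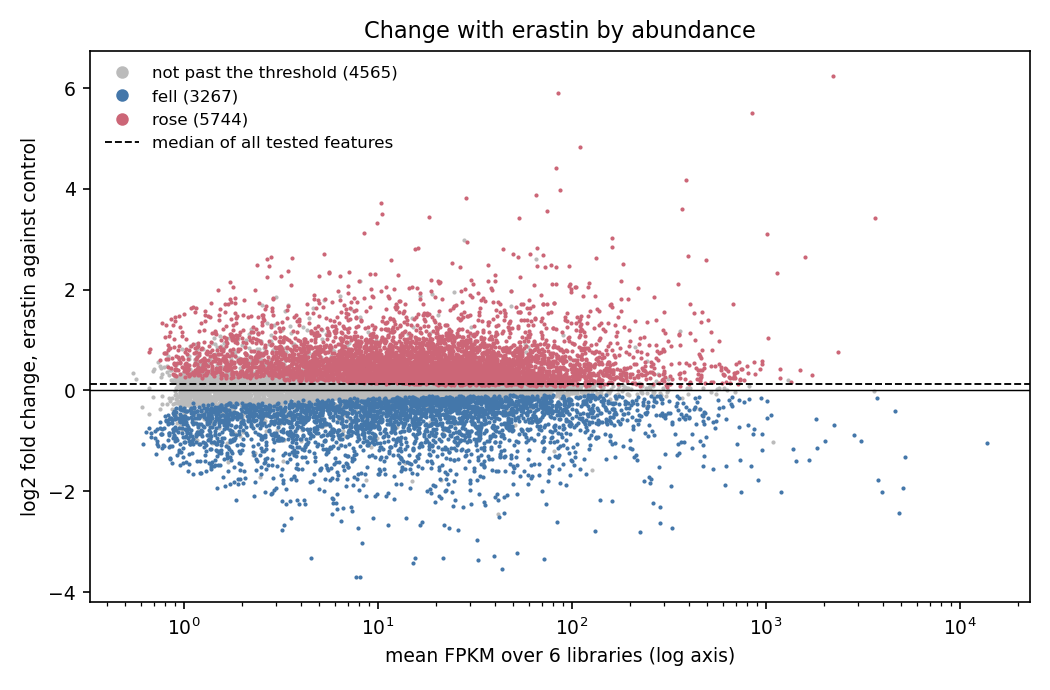
Each point is 1 of 13576 tested features, with the mean FPKM over 6 libraries on a log axis and the log2 fold change of erastin against control on the vertical axis; red points rose, blue points fell and grey points did not pass the adjusted p. The dashed line is the median of all tested features, 0.13, and the 5744 rising features outnumber the 3267 falling ones.

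The feature ENSRNOG00000014117 had the largest increase on the log2(FPKM + 1) scale among features with a mean at or above the median of 12.51 FPKM. It was at 57.0 ± 5.12 FPKM (SD, n = 3) in control and 4391 ± 63.1 FPKM (SD, n = 3) in erastin libraries, 77.0-fold higher, from 926 to 1363 reads per control library and 75747 to 83999 reads per erastin library. Its log2 fold change was 6.25 (SE 0.061, limma adjusted p = 3.27e-09) and its centred value 6.10. It ranked 1660 by abundance in control and 3 in erastin libraries. ENSRNOG00000033153 followed, at 1.91 ± 0.731 FPKM (SD, n = 3) in control and 168 ± 2.51 FPKM (SD, n = 3) in erastin libraries, 88.2-fold higher, which is the larger of both folds in mean FPKM. Its log2 fold change was 5.90 (SE 0.203, limma adjusted p = 5.9e-06) and its centred value 5.78. The control level of ENSRNOG00000033153 rested on 12 to 21 reads per library, against 1411 to 1486 in erastin libraries. Both features were higher in 3 of 3 erastin libraries than in any control library, which the rule for naming features required.

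The feature ENSRNOG00000015075 had the largest decrease on the log2(FPKM + 1) scale under the same rule. It was at 81.1 ± 3.63 FPKM (SD, n = 3) in control and 6.04 ± 0.154 FPKM (SD, n = 3) in erastin libraries, 13.4-fold lower, from 3441 to 4860 reads per control library and 255 to 272 reads per erastin library. Its log2 fold change was -3.54 (SE 0.047, limma adjusted p = 7.1e-09) and its centred value -3.68. ENSRNOG00000060344 was at 28.8 ± 8.35 FPKM (SD, n = 3) in control and 1.77 ± 0.838 FPKM (SD, n = 3) in erastin libraries, 16.3-fold lower and so the larger fall in mean FPKM, with a log2 fold change of -3.43 (SE 0.297, limma adjusted p = 0.000237) and a centred value of -3.55. The erastin level of ENSRNOG00000060344 rested on 6 to 14 reads per library and its control level on 117 to 204. Which of both features fell more rested on single libraries, since ENSRNOG00000015075 and ENSRNOG00000060344 were at -3.55 and -3.61 without control replicate 3 and at -3.54 and -3.66 without erastin replicate 3. The 10 largest increases by the same rule were 12.3-fold to 88.2-fold in mean FPKM, and the 10 largest decreases were 7.10-fold to 16.3-fold. The rule leaves out features whose mean over all libraries is low because they fell. Below the median level 2 features, singled out after their values were seen, fell further, 1 of them Ensembl-numbered. The Ensembl-numbered one went from 15.8 ± 0.996 to 0.302 ± 0.117 FPKM (SD, n = 3), 52.4-fold lower, with 6 to 15 reads per erastin library (log2 fold change -3.69, limma adjusted p = 5.03e-08). The other went from 15.2 ± 0.0576 to 0.242 ± 0.0343 FPKM (SD, n = 3), 63.0-fold lower, with 14 to 17 reads per erastin library (log2 fold change -3.71, limma adjusted p = 1.48e-08). Feature names were not paired with IDs in the sources used here, so no gene symbols are given.

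**Figure D2:**
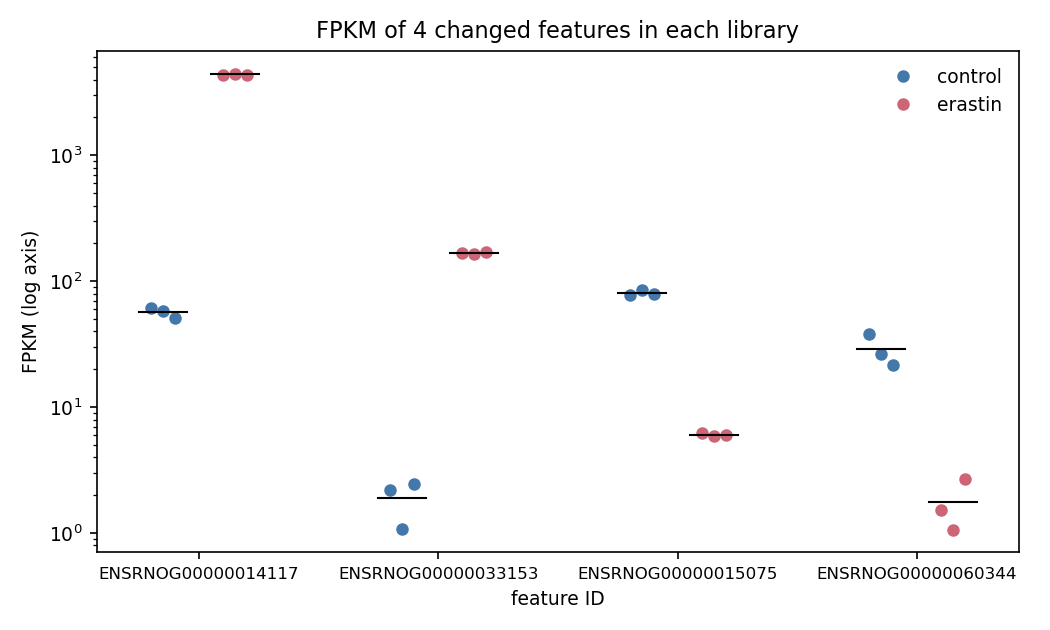
FPKM on a log axis of the 2 rising and 2 falling features named in the text; each point is 1 library, blue for control and red for erastin (n = 3 each), and black lines are group means. No control point overlaps an erastin point, which the rule for naming features required, and ENSRNOG00000014117 moves from a mean of 57.0 to 4391 FPKM.

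Most of the 10 most abundant features fell with erastin. Of the 10 features with the highest mean over 6 libraries, 8 fell, 6 of them at least 2-fold, 1 rose and 1 did not pass the adjusted p in limma. With centred values 9 fell and 1 rose. The most abundant feature fell from 18591 ± 344 to 9059 ± 846 FPKM (SD, n = 3), a log2 fold change of -1.04 (SE 0.063, limma adjusted p = 5.14e-06). The largest fall within these 10, from 8178 ± 331 to 1509 ± 113 FPKM (SD, n = 3), was a log2 fold change of -2.44 (SE 0.057, limma adjusted p = 3.61e-08). The feature that rose went from 621 ± 11.9 to 6708 ± 444 FPKM (SD, n = 3), from rank 82 in control to rank 2 in erastin libraries, with a log2 fold change of 3.43 (SE 0.048, limma adjusted p = 7.76e-09). Of the 100 most abundant features, 49 rose, 44 fell and 7 did not pass. With centred values 40 rose and 47 fell.

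**Figure D3:**
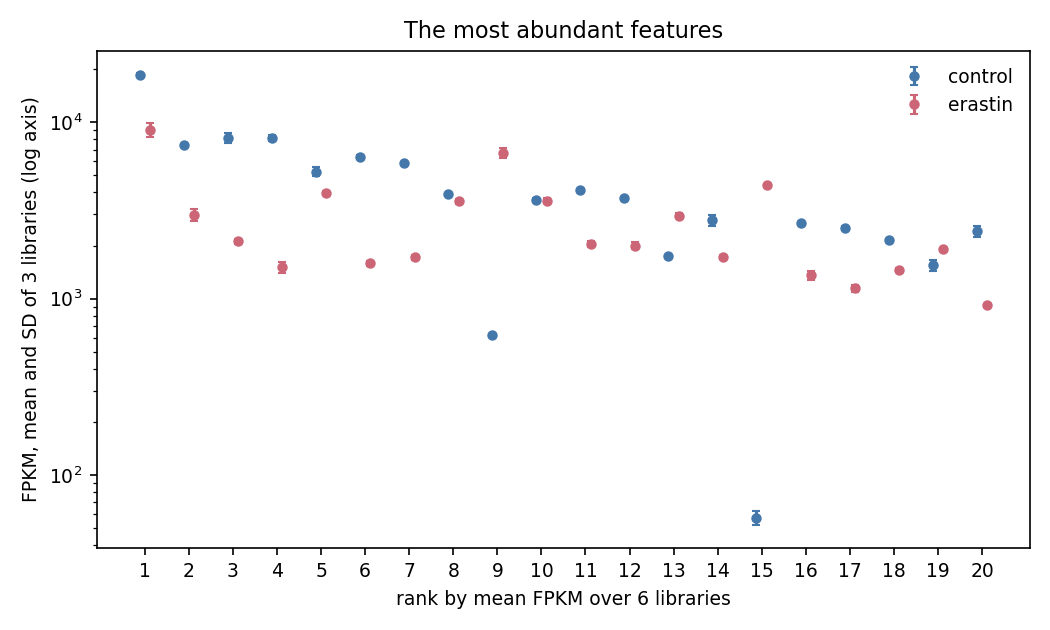
FPKM on a log axis, as mean and SD of 3 libraries, of the 20 features with the highest mean over 6 libraries, ordered by that mean, in control (blue) and erastin (red) cells. Of these 20 features 15 fell and 4 rose, and the feature at rank 15 rises from 57.0 to 4391 FPKM.

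The FPKM were distributed more evenly over the features in erastin than in control libraries. The 10 most abundant features of each library held 13.2 ± 0.156% of its FPKM in control and 7.78 ± 0.0802% in erastin libraries (SD, n = 3), a difference with an exact two-sided permutation p of 0.1, the smallest that 3 against 3 libraries can give. As a share of recovered reads in place of FPKM the difference was -3.47 percentage points, against -5.41 for FPKM. The 100 most abundant held 29.7 ± 0.396% and 23.5 ± 0.164% (SD, n = 3; exact permutation p = 0.1). Of the 10 highest-ranked features in control, 5 were also among the 10 highest in erastin libraries, and of the 100 highest, 70 were. The number of features with a value above 0 was 19095 ± 242 in control and 18970 ± 82.2 in erastin libraries (SD, n = 3), a difference that did not exceed the spread between libraries (exact permutation p = 0.6). At least 1 FPKM was reached by 13333 ± 33.5 features in control and by fewer, 13262 ± 8.62, in erastin libraries (SD, n = 3; exact permutation p = 0.1).

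The balance of rising and falling features differed between levels of abundance. In the lowest of 5 equal groups by mean FPKM, 569 features rose and 653 fell. This group lay at 0.548 to 3.11 FPKM with a median of 35 reads per library, against 1575 reads in the most abundant group. Small changes are harder to call at that level, and the log2(FPKM + 1) scale understates them. In the next groups by increasing abundance the counts were 985 and 610, 1338 and 588, 1456 and 608, and in the most abundant group 1396 and 808. With centred values they were 425 and 774, 706 and 770, 991 and 797, 1043 and 870, and 1066 and 1060. A few features were detected in 1 group alone. With at least 10 reads in every library of the other group, 2 features had 0 reads in all erastin libraries and 3 had 0 reads in all control libraries. Only 1 of the 2 and 1 of the 3 were Ensembl-numbered, and of the 3 only 2 were among the tested features. Against a floor of 3 counts over the group, the largest of these differences was at least 43.7-fold lower, with 40 to 62 reads per control library, and at least 63.0-fold higher, with 47 to 74 reads per erastin library. These bounds cover counting error only, and the features were counted after the values were seen.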

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

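The 4 alternatives added after the data were seen were voom on recovered reads, the same with centring, leaving out the 100 most abundant features, and shares of recovered reads. Across 19 alternatives the number of changed features lay between 1344 and 9308, and in 18 it was within 1.5 times of 9011. The exception was the minimum absolute log2 fold change of 1, which left 1344 features, 699 higher and 645 lower, by construction. Leaving out 1 library gave 8064 to 8335 changed features. The share of changed features that rose was 63.7%, and it was 49.8% with centring, 51.8% with quantile normalization, 49.6% with voom and centring and 52.0% with the minimum fold. Voom without centring gave 63.8%. Of the 9011 changed features, 8815 were called in the same direction by voom on recovered reads and 0 in the opposite one. Quantile normalization called 2 in the opposite direction. The fall in the share of FPKM held by the 10 most abundant features was -5.41 percentage points, and -3.47 as a share of recovered reads, where feature length no longer weighs. The 4 named features kept their direction and an adjusted p under 0.05 in every alternative that tested them, with log2 fold changes of 6.10 to 6.62 for ENSRNOG00000014117, 5.67 to 6.57 for ENSRNOG00000033153, -3.89 to -3.51 for ENSRNOG00000015075 and -4.16 to -3.22 for ENSRNOG00000060344. With pseudocounts of 0.1 and 0.01 and with voom, the order within each pair of named features was the opposite, with ENSRNOG00000033153 and ENSRNOG00000060344 changing more. The order of the falling pair was also the opposite without control replicate 3 and without erastin replicate 3. The alternatives for count tables, gene lists and the authors' own comparison were not run.

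With the replicate block, 8768 features changed, 5583 higher and 3185 lower. Libraries with the same number were not paired by the labels, and the correlations of their deviations were -0.03, 0.07 and 0.03, within or close to the range of -0.07 to 0.04 between different numbers. Not every library correlated best with the one of its own number. The simulations recovered 60% of 1.5-fold changes and 87% of 2-fold changes, and neither depth nor the number of libraries was varied in them. The simulated tables held far fewer changed features than were called in the data, so these shares do not carry over to the data.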

Other observations

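Centring was an alternative fixed before the data were examined, but its use below as a test of an explanation was chosen after its result was seen. Leaving out the 100 most abundant features and the comparison of the share of large decreases with matched lists were chosen after the data were seen. Features that rose held 35.2 ± 0.33% of the FPKM in control and 55.4 ± 0.62% in erastin libraries, and features that fell held 47.9 ± 0.42% and 27.4 ± 0.62% (SD, n = 3). These shares follow from the selection of the features and were not tested.

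More features rose than fell, 5744 against 3267. A candidate explanation is the scaling to library totals, since the most abundant features lost share and all others then gain. Centring gave 49.8% rising, but it sets the median change to 0 by construction and so cannot decide. Leaving out the 100 most abundant features and rescaling gave 56.2% rising (4806 against 3742), between the bounds set for and against these features as the whole cause, and the median log2 fold change went from 0.14 to 0.06. The greater depth of control replicate 2 is argued against, since without that library 66.0% rose. The total RNA of the cells was not measured, and scaling to library totals divides it out. These values therefore do not tell whether more features rose than fell per cell.

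Features named outside the Ensembl numbering changed less upward than the others. Their median log2 fold change was 0.037 against 0.14 for Ensembl-numbered features (camera p = 0.0121 with a preset correlation and p = 0.0399 with an estimated correlation). Lower abundance and other counted length may account for this median, which lay at percentile 73.75 of 10000 matched random lists. The share that fell at least 2-fold was 10.8% in this class, against 3.6% to 6.5% in the middle 95% of the matched lists and 8.0% at most. Matching on mean level and counted length thus did not remove this excess, though matching in 10 bins leaves differences within a bin. What these features are was not given in the sources used here, so other technical sources, such as reads shared with neighbouring genes, stay open beside an effect of erastin.

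The longest features stood apart from the others. In 5 equal groups by increasing counted length the median log2 fold change was 0.15, 0.17, 0.15, 0.13 and 0.06, and 63.2%, 67.5%, 66.0%, 65.0% and 57.0% of the changed features rose. In the longest group 111 features rose and 168 fell at least 2-fold, and in the shortest 178 rose and 133 fell. Within the 5 groups by increasing abundance, the median log2 fold change of the longest minus that of the shortest features was -0.23, -0.04, -0.10, -0.10 and -0.08. By the bounds set beforehand, abundance as the source was to leave differences under 0.05 in every group. This held only in the second group. To exclude abundance, differences above 0.1 in the same direction were needed in all 5 groups. All 5 were negative, but not all passed that bound, so neither bound was met. Within the control and erastin groups, the longest minus the shortest features gave a single value for each library, not split by abundance. These values were -0.023 to 0.011. Whether RNA fragmentation or transcript processing is a source was not tested.

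The grouping into control and erastin gave 9011 changed features, and the highest number in the other 9 of the 10 splits of the 6 libraries into 3 and 3 was 1. With 10 splits the share with as large a count is never under 0.1. Each of the other 9 splits mixes control and erastin libraries on both sides, so the difference between the groups adds to the spread within them. Few calls were bound to follow, and the splits do not tell how many of the 9011 calls are false.

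Single libraries stood apart from both others of their group by more than 2-fold in few of the 6788 features at or above the median level, with at most 12 features above and 9 below in any library. Control replicate 2 had 9 features below both other control libraries. The most abundant of these 9 was at 580.5 FPKM there and at 1923 and 2107 FPKM in the other control libraries. In erastin libraries it was at 586, 763 and 613 FPKM.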
